A study of Arabidopsis thaliana with 24 samples.

How the data were processed

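The 24 libraries came from roots of Arabidopsis thaliana, Col-0 and the line labelled sgn3 myb36, at a control point labelled CK and 3, 6 and 10 h after inoculation with CHA0. RNA was extracted with Trizol, treated with DNase and depleted of ribosomal RNA, and strand-specific libraries were built with a directional kit, per the labels' protocols. The authors deposited 1 table of raw read counts per gene, whole numbers that were not normalised, with 32833 Arabidopsis gene codes and 1 column for each of the 24 libraries. Trimmomatic 0.32, STAR 2.7.9a and DESeq2 1.38.0 and the genome TAIR10 are named in the submitters' processing notes, without their roles. The counting step, the gene annotation and the strand setting are not given in the sources used here, so genes that overlap or are near copies of each other may share reads. Column names were matched to samples by the labels.

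A total of 25702 genes had a count in at least 1 library. The reference table of assembly TAIR10.1 named 32548 of the 32833 gene codes, and 285 were not in it. It was used for symbols, gene types and the order of neighbouring genes, and no coordinates were taken from it. Protein-coding genes took 98.9 to 99.6% of the counts of a library, mitochondrial and chloroplast genes 0.0531 to 0.479%, ribosomal RNA genes 0.0326 to 0.203% and the 10 most abundant genes 2.65 to 4.29%. Totals of 8786742 to 10876749 counts mean that a gene at 3 counts in a library stands at 0.276 to 0.341 CPM. Pairs of replicates were tested for duplicates by chi-square over genes with at least 20 counts in the pair, and no sample was left out.

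Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 8 groups, which left 20405, and libraries were scaled by TMM factors of 0.946 to 1.063. One quasi-likelihood model with a mean for each of the 8 groups was fitted to all 24 libraries, with 16 residual degrees of freedom and a common dispersion of 0.0551 (biological coefficient of variation 0.235). The 13 contrasts set 3, 6 and 10 h against CK in each genotype, the genotypes against each other at each of 4 times, and the response of sgn3 myb36 against that of Col-0 at 3, 6 and 10 h. A joint test covered the 3 interactions. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Time and inoculation cannot be separated within a genotype, because no uninoculated roots at 3, 6 or 10 h were analysed here. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

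The groups, the tests, the naming rule, 33 gene lists and the first group of alternatives below were fixed before the data were examined. The lists held 467 planned members, of which 451 were matched by gene code and symbol and 16 were left out. They were pattern-triggered immunity, camalexin and tryptophan-derived defence, indole glucosinolates, aliphatic glucosinolates, salicylic acid, jasmonate, ethylene, abscisic acid, auxin response, cytokinin response, Casparian strip, suberin, monolignols and lignin, iron deficiency, phosphate starvation, nitrate and ammonium uptake, glutamine and amino acid metabolism and transport, sugar transport, aquaporins, hypoxia, mitochondrial dysfunction and cyanide detoxification, xenobiotic detoxification, unfolded protein response, heat shock, touch, handling and cold, circadian clock, morning, circadian clock, afternoon and evening, mitotic cell cycle, photosynthetic tissue, root hair, xylem, phloem, and root cap. The root cap list had fewer than 5 tested members and was not tested. For the other 32 lists, camera (limma 3.58.1) compared each list with all other tested genes on log2 CPM with a prior count of 2, a preset correlation of 0.01 and adjustment over 416 tests. Beside it stand the result with a correlation estimated from the data, and counts of members adjusted over the list alone. Median, mean and camera direction of a list had the same sign in each of the 221 called list tests and differed in 44 of the 195 not called.

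The naming rule took, in each contrast, the 4 highest and 4 lowest log2 fold changes among called protein-coding genes with a symbol, a mean of at least 5 CPM in the higher group and, outside the interactions, all 3 libraries of one group above all 3 of the other. The text gives some of these. It also took up to 4 called members of each list with the smallest p, and SGN3 and MYB36 always. Where a group had no count, the fold is a bound against a floor of 3 counts over its 3 libraries. Where it had 1 to 3 counts, the ratio is given with a 95% counting interval. Such bounds and intervals cover counting error only.

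Alternatives were DESeq2 size factors, library totals as the only scaling, no filter on low counts, at least 50 counts in 3 samples, nuclear protein-coding genes alone, an adjusted p under 0.01, a log2 fold change of at least 1, only the groups compared, a replicate block, each library left out in turn, and DESeq2 1.42.0. A further 2 were chosen after seeing the data, namely leaving out 3 chosen libraries, and the mean photosynthetic level of each library as a covariate. Further lists chosen after seeing the data were shoot epidermis and guard cells, ferritin, sulfur deficiency and sugar starvation.

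The code was tested on simulated counts with known changes. For Col-0 3 h against CK over 19567 genes, edgeR recovered 61% of 100 genes changed 2-fold and 100% of 100 changed 4-fold. Of its calls 3.6% were false. In a simulated interaction at 6 h it recovered 27% and 91%, with 6.3% false, and DESeq2 recovered 72% and 100% in the first comparison over 20405 genes, with 14% false. A shifted list of 20 genes was called by camera, and 0 of 100 unchanged lists were, which did not test its preset correlation. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, permutation tests and figures.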

Results

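RNA was sequenced from roots of Arabidopsis thaliana of 2 genotypes, the wild type Col-0 and a line labelled sgn3 myb36, in hydroponic culture. SGN3 is a receptor kinase that monitors the Casparian strip, the ring of lignin in the endodermal cell wall that seals the apoplast, and MYB36 is the transcription factor that switches on the genes building it. Roots were taken at a control point labelled CK, 0 h in the study design, and 3, 6 and 10 h after inoculation with CHA0, a root-colonising strain of Pseudomonas protegens. Each of the 8 groups held 3 libraries, 24 in all. The libraries held 8786742 to 10876749 counts (median 9856746), and 20238 to 22119 genes had a count in a library. Replicates of a group correlated at r of 0.914 to 0.976 across genes on the log2 scale, and no pair of replicates was as close as sampling noise alone would make it (chi-square per gene 7.61 to 40.5 over 24 pairs). Libraries labelled sgn3 myb36 are called sgn3 myb36 throughout. Levels are in CPM, counts relative to the scaled library total, and given as mean ± SD of 3 libraries, and log2 fold changes (log2FC) are given ± their standard error, with adjusted p from edgeR's quasi-likelihood test.

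SGN3 and MYB36 themselves were examined first, because they test the genotype labels. SGN3 (AT4G20140) lay at 14.5 to 42.8 CPM in the 12 Col-0 libraries and at 7.69 to 22.1 CPM in the 12 sgn3 myb36 libraries. Its group means in Col-0 were 19.4 ± 4.01 CPM at CK, 18.8 ± 7.24 at 3 h, 33.4 ± 8.59 at 6 h and 34.0 ± 4.25 at 10 h, against 9.65 ± 3.24, 11.9 ± 2.61, 18.3 ± 3.89 and 15.8 ± 2.64 CPM in sgn3 myb36. It was lower in sgn3 myb36 at CK (log2FC -1.0 ± 0.28, adjusted p = 0.0193) and at 10 h (-1.11 ± 0.27, adjusted p = 0.00808) and did not pass the test at 3 h (-0.66 ± 0.28, adjusted p = 0.119) or 6 h (-0.87 ± 0.27, adjusted p = 0.063). The call at CK ended without Col-0 CK replicate 1 (adjusted p = 0.0593), Col-0 CK replicate 2 (adjusted p = 0.0667), sgn3 myb36 CK replicate 2 (adjusted p = 0.077) or sgn3 myb36 CK replicate 3 (adjusted p = 0.0879). MYB36 (AT5G57620) went the other way, with 17.7 ± 2.71, 12.8 ± 2.17, 19.8 ± 3.27 and 21.4 ± 5.00 CPM in Col-0 against 36.8 ± 10.4, 44.7 ± 7.96, 38.9 ± 4.53 and 62.3 ± 6.27 CPM in sgn3 myb36. It was higher in the libraries labelled sgn3 myb36 at CK (log2FC 1.06 ± 0.21, adjusted p = 0.00251), 3 h (1.80 ± 0.21, adjusted p = 2.42e-05), 6 h (0.97 ± 0.21, adjusted p = 0.00652) and 10 h (1.54 ± 0.21, adjusted p = 3.04e-05). A count per gene does not show which part of a transcript the reads cover. CASP1 (AT2G36100), a membrane scaffold protein of the Casparian strip, separated the labels, as it lay at 21.5 to 136 CPM in Col-0 and at 0.767 to 3.23 CPM in sgn3 myb36.

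**Figure D1:**
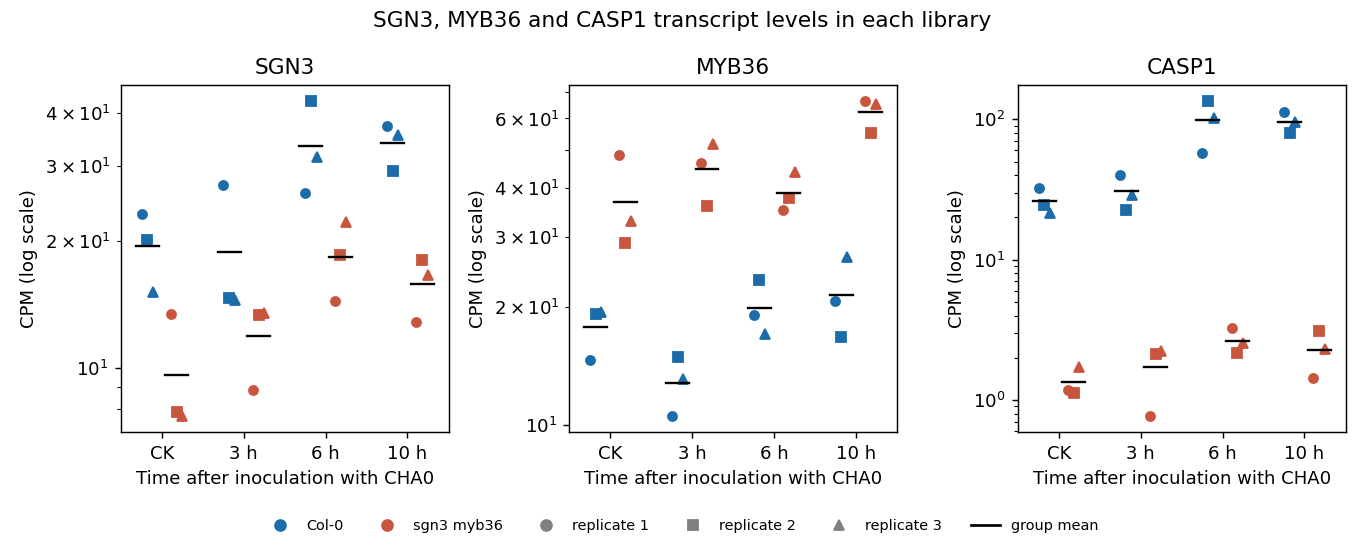
CPM on a log scale of SGN3, MYB36 and CASP1 against time after inoculation, 1 point per library and a black bar for the mean of each group of 3. CASP1 lies at 21.5 to 136 CPM in the Col-0 libraries and at 0.767 to 3.23 CPM in the sgn3 myb36 libraries, while MYB36 is higher in sgn3 myb36 at every time.

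The first principal component of the 500 most variable genes held 58.3% of their variance and the second 15.3%. Col-0 CK libraries lay at -51.5 to -39.3 on the first component and Col-0 10 h libraries at -7.47 to 14.6, and sgn3 myb36 CK libraries lay at -35.8 to -31.6 and sgn3 myb36 10 h libraries at 42.1 to 60.8. Libraries of a group differed in the mean level of some fixed gene lists, and 3 of the 24 were chosen by these levels, after seeing the data, to be left out as an alternative. The mean of the photosynthetic tissue list was 8.88 log2 CPM in sgn3 myb36 CK replicate 1, where its genes took 1.09% of the counts, against 7.63 and 6.78 in replicates 2 and 3. The mean of the hypoxia list was 6.27 log2 CPM in sgn3 myb36 6 h replicate 1 against 9.11 and 8.55 in replicates 2 and 3, and 6.64 in Col-0 10 h replicate 1 against 5.00 and 4.92. Other libraries lay as far from their group on the photosynthetic list and were not among the 3 chosen. It stood at 5.25 in Col-0 3 h replicate 1 against 7.05 and 7.26, and at 7.75 in Col-0 6 h replicate 3 against 5.94 and 5.91. In sgn3 myb36 it stood at 4.49 in 3 h replicate 2 against 7.03 and 6.06, at 4.39 in 6 h replicate 2 against 6.80 and 5.91, and at 3.82 in 10 h replicate 3 against 6.00 and 5.59.

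**Figure D2:**
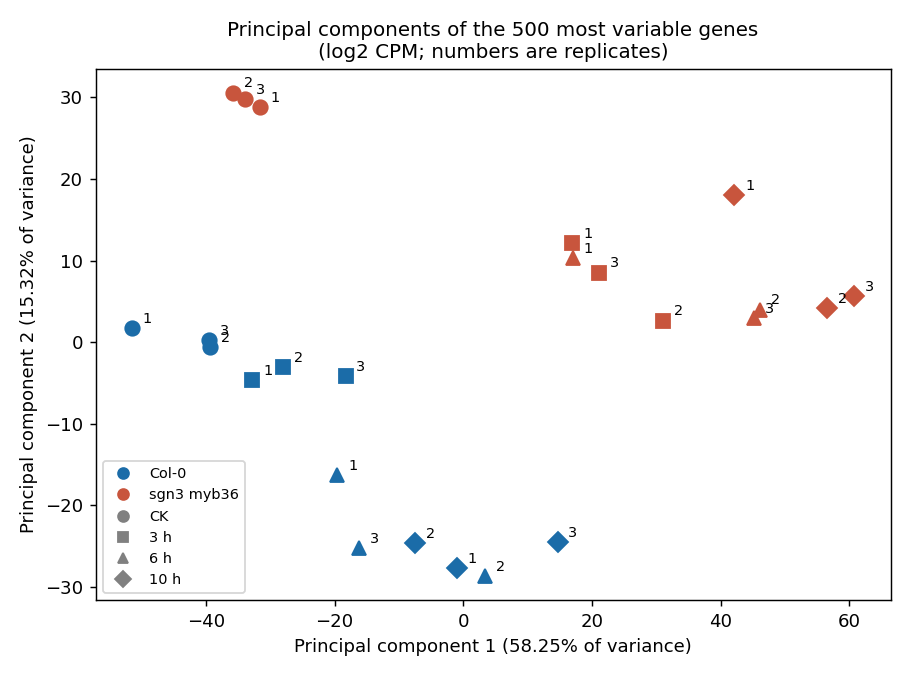
Scores of the 24 libraries on the first and second principal components of log2 CPM, with colour for genotype, shape for time and a number for the replicate. Along the first component sgn3 myb36 CK libraries lie at -35.8 to -31.6 and sgn3 myb36 10 h libraries at 42.1 to 60.8, whereas the Col-0 10 h libraries reach 14.6.

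The response of wild-type roots was read by setting each later time against CK within Col-0. At 3 h, genes of glucosinolates, the sulfur-rich defence compounds of the Brassicaceae, had risen. 7 of the 16 indole glucosinolate genes (11 adjusted over the list alone) rose, among them the regulator MYB34 (AT5G60890, log2FC 1.2 ± 0.23, adjusted p = 0.00197) and the core pathway enzyme SUR1 (AT2G20610, log2FC 1.17 ± 0.23, adjusted p = 0.00267). 3 were called without Col-0 CK replicate 1 or 3 and 4 without Col-0 3 h replicate 1. The indole glucosinolate list gave adjusted p = 4.2e-07 by camera and 0.367 with an estimated correlation. 6 of the 12 aliphatic glucosinolate genes (6 adjusted over the list alone) rose, including the regulator MYB28 (AT5G61420, log2FC 1.66 ± 0.35, adjusted p = 0.00515) and the sulfotransferase SOT17 (AT1G18590, log2FC 2.25 ± 0.32, adjusted p = 0.000124). The aliphatic glucosinolate list gave adjusted p = 1.01e-06 by camera and 0.379 with an estimated correlation. 5 of the 12 phosphate starvation genes (6 adjusted over the list alone) rose, including the phosphate transporter PHT1;4 (AT2G38940, log2FC 1.32 ± 0.29, adjusted p = 0.00705) and PS3 (AT3G47420, log2FC 2.05 ± 0.32, adjusted p = 0.000356). The phosphate starvation list gave adjusted p = 8.84e-05 by camera and 0.367 with an estimated correlation. 4 of the 16 aquaporin genes (5 adjusted over the list alone) fell, such as PIP1;5 (AT4G23400, log2FC -1.08 ± 0.22, adjusted p = 0.00469). At most 2 were called without Col-0 3 h replicate 1, 2 or 3 or Col-0 CK replicate 1 or 2. The aquaporin list gave adjusted p = 0.00244 by camera and 0.488 with an estimated correlation. In the pattern-triggered immunity list, 2 of 29 genes rose (3 adjusted over the list alone) and 27 were not called. At most 1 was called without Col-0 3 h replicate 1 or 3 or Col-0 CK replicate 1, 2 or 3. The pattern-triggered immunity list gave adjusted p = 0.000141 by camera and 0.505 with an estimated correlation. The glutamate dehydrogenase genes GDH1 (AT5G18170, log2FC -1.57 ± 0.15, adjusted p = 3.28e-06) and GDH2 (AT5G07440, log2FC -1.35 ± 0.23, adjusted p = 0.000819) fell, while the list of 20 glutamine and amino acid genes did not pass, with 1 higher and 2 lower (1 and 2 adjusted over the list alone). The glutamine and amino acid list gave adjusted p = 0.435 by camera.

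The largest rises in Col-0 at 3 h by the naming rule were led by ANAC042 (AT2G43000, log2FC 3.95 ± 0.95, adjusted p = 0.0132, not called at adjusted p = 0.0749, 0.0735 and 0.109 without Col-0 CK replicates 1 and 3 or Col-0 3 h replicate 3 in turn, 5.40 without Col-0 CK replicate 2), a NAC transcription factor. Next came UGT84A1 (AT4G15480, log2FC 3.46 ± 0.69, adjusted p = 0.00356, 4.90 without Col-0 CK replicate 2), a glucosyltransferase of hydroxycinnamic acids. The largest fall was that of GLR2.3 (AT2G24710, log2FC -2.71 ± 0.70, adjusted p = 0.0211, not called at adjusted p = 0.0575, 0.0782, 0.114 and 0.0537 without Col-0 CK replicates 2 and 3 or Col-0 3 h replicates 1 and 2 in turn), a glutamate receptor family gene. It was followed by OXS3 (AT5G56550, log2FC -2.69 ± 0.45, adjusted p = 0.000753). Another large fall was that of bZIP1 (AT5G49450, log2FC -2.57 ± 0.52, adjusted p = 0.00393, -3.36 without Col-0 3 h replicate 3), a transcription factor of low-energy signalling that went from 137 ± 29.9 to 23 ± 17.2 CPM. In all, 1281 of 20405 tested genes were called, 652 higher and 629 lower, 611 of them by at least 2-fold. The count was 1491 without the 3 chosen libraries, 844 without Col-0 CK replicate 2, 692 without Col-0 CK replicate 3 and 585 without Col-0 3 h replicate 1.

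At 6 and 10 h the Col-0 response included immunity, iron, nitrate, lignin and root hair genes. 13 of the 29 pattern-triggered immunity genes (21 adjusted over the list alone, 6 without Col-0 CK replicate 1 or Col-0 6 h replicate 2) rose at 6 h, among them the ubiquitin ligase PUB22 (AT3G52450, log2FC 2.07 ± 0.42, adjusted p = 0.00217) and WRKY22 (AT4G01250, log2FC 2.15 ± 0.33, adjusted p = 0.000217). The pattern-triggered immunity list gave adjusted p = 8.39e-08 by camera and 0.416 with an estimated correlation. At 10 h 22 rose (25 adjusted over the list alone). 8 were called without Col-0 10 h replicate 3 and 12 without Col-0 CK replicate 1. The pattern-triggered immunity list gave adjusted p = 2.87e-09 by camera and 0.394 with an estimated correlation. 6 of the 20 salicylic acid genes (7 adjusted over the list alone, 3 without Col-0 10 h replicate 3) rose at 10 h, including EDS5 (AT4G39030, log2FC 1.57 ± 0.35, adjusted p = 0.00319), the plastid exporter of its precursor. The salicylic acid list gave adjusted p = 0.000614 by camera and 0.488 with an estimated correlation. 7 of the 22 jasmonate genes (9 adjusted over the list alone, 4 without Col-0 10 h replicate 3) rose at 10 h, among them the synthesis gene AOC3 (AT3G25780, log2FC 2.61 ± 0.35, adjusted p = 2.99e-05). The jasmonate list gave adjusted p = 0.00197 by camera and 0.442 with an estimated correlation. 8 of the 11 nitrate and ammonium uptake genes (9 adjusted over the list alone) rose at 6 h, such as NRT2.1 (AT1G08090, log2FC 4.31 ± 0.61, adjusted p = 0.000111), a high-affinity nitrate transporter. 5 were called without Col-0 CK replicate 1 or 3 or Col-0 6 h replicate 2. The nitrate and ammonium uptake list gave adjusted p = 1.11e-05 by camera and 0.367 with an estimated correlation. 13 of the 17 monolignol and lignin genes (14 adjusted over the list alone) rose at 6 h, such as CAD4 (AT3G19450, log2FC 1.03 ± 0.17, adjusted p = 0.000414). 7 were called without Col-0 CK replicate 1 and 8 without Col-0 6 h replicate 2. The monolignol and lignin list gave adjusted p = 1.67e-07 by camera and 0.373 with an estimated correlation. All 7 root hair genes rose at 6 h, among them EXPA18 (AT1G62980, log2FC 2.59 ± 0.53, adjusted p = 0.00222), a wall-loosening protein (7 adjusted over the list alone). The root hair list gave adjusted p = 2.36e-05 by camera and 0.373 with an estimated correlation.

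5 of the 8 Casparian strip genes (6 adjusted over the list alone, 3 without Col-0 CK replicate 1) rose in Col-0 at 6 h, including CASP1, from 26.2 ± 5.74 to 98.4 ± 39.3 CPM (log2FC 1.91 ± 0.29). The Casparian strip list gave adjusted p = 0.00152 by camera and 0.367 with an estimated correlation. 16 of the 19 iron deficiency genes (16 adjusted over the list alone) rose at 10 h, among them FIT (AT2G28160, log2FC 1.68 ± 0.33, adjusted p = 0.00107), the regulator of iron uptake. 7 were called without Col-0 CK replicate 1, 9 without Col-0 CK replicate 3 and 10 without Col-0 10 h replicate 1. The iron deficiency list gave adjusted p = 7.35e-05 by camera and 0.373 with an estimated correlation. 7 of the 13 hypoxia genes (7 adjusted over the list alone) rose at 10 h (camera adjusted p = 0.0766), where the list lay at 6.64 log2 CPM in replicate 1 against 4.92 in replicate 3. 2 were called without Col-0 10 h replicate 1, 3 without Col-0 CK replicate 2 or 3 and 4 without Col-0 CK replicate 1. Without the 3 chosen libraries, 5 of these genes rose and 1 fell.

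The naming rule took the same pair as the largest rises in Col-0 at 6 and 10 h. They were the cytochrome P450 gene CYP705A3 (AT4G15360, at least 65.9-fold higher, adjusted p = 0.00174, 43.3-fold without Col-0 6 h replicate 3) and the glutathione transferase gene GSTU12 (AT1G69920, 151-fold higher, counting interval 26.7 to 5991, adjusted p = 0.00613, 78.8-fold without Col-0 6 h replicate 2) at 6 h. At 10 h they were CYP705A3 (at least 97.5-fold higher, adjusted p = 0.000609, 61.9-fold without Col-0 10 h replicate 1) and GSTU12 (202-fold higher, counting interval 35.8 to 8012, adjusted p = 0.00232). Among the largest falls were GAT1_2.1 (AT1G15040, log2FC -3.20 ± 0.56, adjusted p = 0.000705), a glutamine amidotransferase gene, at 6 h and SEN1 (AT4G35770, log2FC -4.00 ± 0.65, adjusted p = 0.000201), a gene induced by darkness, at 10 h. Called genes numbered 3600 at 6 h (2280 higher, 1320 lower, 1608 by at least 2-fold) and 4632 at 10 h (2852 higher, 1780 lower, 2098 by at least 2-fold), and 3984 and 3644 without the 3 chosen libraries. The 6 h count was 1848 without Col-0 CK replicate 1, 2284 without Col-0 CK replicate 3 and 1533 without Col-0 6 h replicate 2, and the 10 h count was 2804 without Col-0 CK replicate 1, 3007 without Col-0 10 h replicate 1 and 2899 without Col-0 10 h replicate 3.

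**Figure D3:**
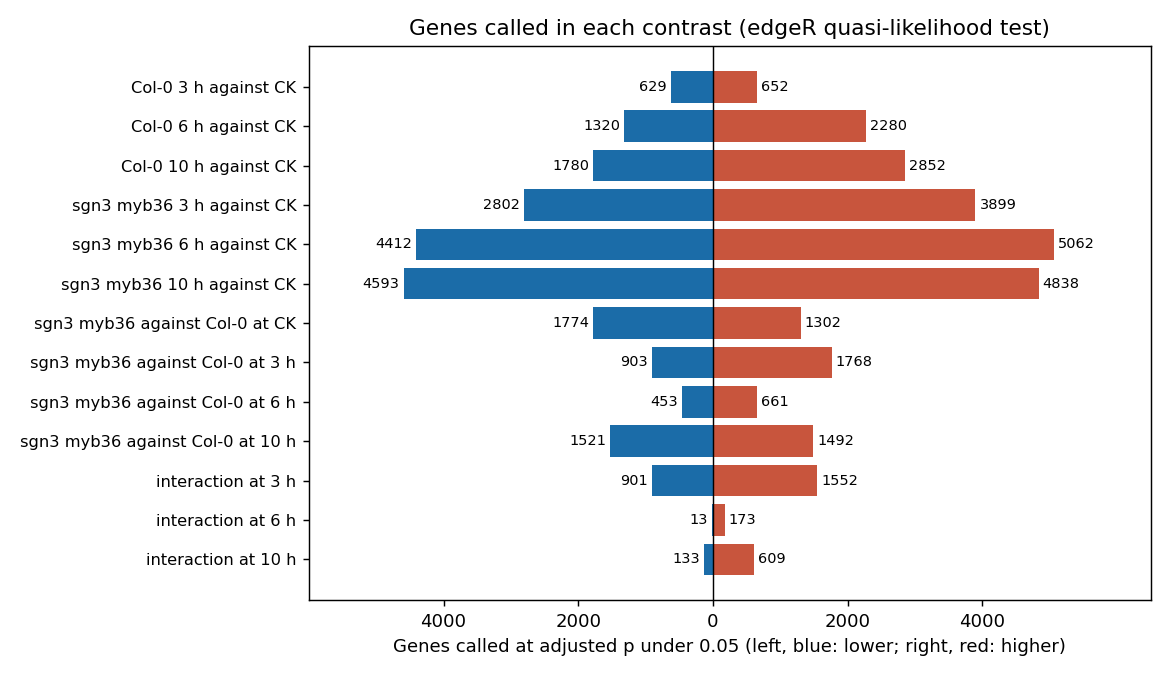
Numbers of genes called at an adjusted p under 0.05 in each of the 13 contrasts, higher to the right in red and lower to the left in blue. The sgn3 myb36 responses hold 6701, 9474 and 9431 called genes at 3, 6 and 10 h, the Col-0 responses 1281, 3600 and 4632.

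Within sgn3 myb36, the same comparison asked how the line responds after inoculation. 27 of the 29 pattern-triggered immunity genes (28 adjusted over the list alone) rose at 3 h, and PUB22 went from 7.61 ± 2.03 CPM at CK to 102 ± 27.2 CPM (log2FC 3.73 ± 0.46). The pattern-triggered immunity list gave adjusted p = 3.92e-12 by camera and 0.373 with an estimated correlation. 16 of the 20 salicylic acid genes (18 adjusted over the list alone) rose at 3 h, among them the immune regulators PAD4 (AT3G52430, log2FC 1.89 ± 0.28, adjusted p = 7.22e-05) and EDS1 (AT3G48090, log2FC 1.06 ± 0.21, adjusted p = 0.000745). The salicylic acid list gave adjusted p = 1.97e-06 by camera and 0.416 with an estimated correlation. 13 of the 22 jasmonate genes (15 adjusted over the list alone) rose, including AOC3 (log2FC 2.07 ± 0.34). The jasmonate list gave adjusted p = 2.35e-05 by camera and 0.373 with an estimated correlation. 9 of the 16 ethylene genes (10 adjusted over the list alone) rose, such as ACS6 (AT4G11280, log2FC 3.07 ± 0.56, adjusted p = 0.000419) of ethylene synthesis. The ethylene list gave adjusted p = 0.000185 by camera and 0.394 with an estimated correlation. 14 of the 17 camalexin and tryptophan-derived defence genes (15 adjusted over the list alone) rose at 6 h, including CYP79B2 (AT4G39950, log2FC 2.96 ± 0.39, adjusted p = 7.89e-06), which makes a common precursor. The camalexin and tryptophan list gave adjusted p = 4.14e-05 by camera and 0.426 with an estimated correlation.

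Genes of low oxygen, detoxification, mitochondrial stress and heat rose in sgn3 myb36. All 13 hypoxia genes rose at 6 h, with PDC1 (AT4G33070, log2FC 7.28 ± 0.75, adjusted p = 1.05e-06), pyruvate decarboxylase of fermentation, and the haemoglobin HB1 (AT2G16060, log2FC 4.83 ± 0.55, adjusted p = 2.21e-06) among them (13 adjusted over the list alone). The hypoxia list gave adjusted p = 1.81e-07 by camera and 0.394 with an estimated correlation. This list stood apart in sgn3 myb36 6 h replicate 1, at 6.27 log2 CPM against 9.11 and 8.55. At 10 h, 12 of the 13 xenobiotic detoxification genes (12 adjusted over the list alone) rose, among them the glutathione transferase GSTU24 (AT1G17170, log2FC 4.4 ± 0.39, adjusted p = 6.21e-08). The xenobiotic detoxification list gave adjusted p = 3.28e-11 by camera and 0.204 with an estimated correlation. 8 of the 9 genes of mitochondrial dysfunction and cyanide detoxification (8 adjusted over the list alone) rose at 10 h, among them AOX1A (AT3G22370, log2FC 4.68 ± 0.43, adjusted p = 1.03e-07), the alternative oxidase. The mitochondrial dysfunction list gave adjusted p = 1.15e-05 by camera and 0.274 with an estimated correlation. All 7 heat shock genes rose at 10 h, including HSP101 (AT1G74310, log2FC 4.42 ± 0.38, adjusted p = 4.81e-08) (7 adjusted over the list alone). The heat shock list gave adjusted p = 6.47e-07 by camera and 0.259 with an estimated correlation. 7 of the 9 genes of touch, handling and cold (9 adjusted over the list alone) rose at 6 h, such as CML38 (AT1G76650, log2FC 4.04 ± 0.61, adjusted p = 3.09e-05). The touch, handling and cold list gave adjusted p = 0.000929 by camera and 0.442 with an estimated correlation. 13 of the 17 suberin genes (13 adjusted over the list alone) rose at 10 h, with FAR5 (AT3G44550, log2FC 3.54 ± 0.34, adjusted p = 1.53e-07), which makes fatty alcohols of this wall polymer, among them. The suberin list gave adjusted p = 2.27e-05 by camera and 0.394 with an estimated correlation. 6 of the 13 auxin response genes (6 adjusted over the list alone) rose at 10 h, including GH3.3 (AT2G23170, log2FC 2.84 ± 0.43, adjusted p = 2.58e-05). 3 were called without sgn3 myb36 CK replicate 3 or sgn3 myb36 10 h replicate 2. The auxin response list gave adjusted p = 0.015 by camera and 0.439 with an estimated correlation. Of 6 phloem genes, SEOR1 (AT3G01680, log2FC 1.84 ± 0.36, adjusted p = 0.000396) rose at 6 h (1 adjusted over the list alone). The phloem list gave adjusted p = 0.321 by camera.

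Division, water transport and photosynthetic genes fell in sgn3 myb36. 15 of the 18 mitotic cell cycle genes (17 adjusted over the list alone) fell at 3 h, among them the mitotic kinase CDKB2;1 (AT1G76540, log2FC -1.09 ± 0.15, adjusted p = 4.95e-05). The mitotic cell cycle list gave adjusted p = 8.89e-09 by camera and 0.373 with an estimated correlation. 13 of the 16 aquaporin genes (13 adjusted over the list alone) fell at 10 h, including PIP1;1 (AT3G61430, log2FC -2.28 ± 0.22, adjusted p = 1.68e-07) and TIP2;2 (AT4G17340, log2FC -2.95 ± 0.29, adjusted p = 1.67e-07). The aquaporin list gave adjusted p = 4.88e-07 by camera and 0.373 with an estimated correlation. 13 of the 15 photosynthetic tissue genes (15 adjusted over the list alone) fell at 10 h, among them PSBO1 (AT5G66570, log2FC -2.25 ± 0.54, adjusted p = 0.00183, -1.50 without sgn3 myb36 CK replicate 1). The photosynthetic tissue list gave adjusted p = 0.000274 by camera and 0.533 with an estimated correlation. This list stood highest in sgn3 myb36 CK replicate 1, at 8.88 log2 CPM against 7.63 and 6.78. Without that library 5 of its genes fell at 10 h. Beside it, 6 markers of shoot epidermis and guard cells, chosen after seeing the data, had a median log2FC of -1.95 at 10 h (-2.08 with genes at their bound), with 1 of 6 called lower, and the median ranged from -3.79 to -0.22 with 1 library left out.

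The largest rises in sgn3 myb36 by the naming rule were those of BGLU27 (AT3G60120, at least 99-fold higher, adjusted p = 0.000551), a beta-glucosidase gene, and CYP71B22 (AT3G26200, at least 93.3-fold higher, adjusted p = 0.00227, 60.8-fold without sgn3 myb36 3 h replicate 1) at 3 h. At 6 h they were those of SRO4 (AT3G47720, at least 246-fold higher, adjusted p = 0.000119, 157-fold without sgn3 myb36 6 h replicate 2) and GAD4 (AT2G02010, at least 156-fold higher, adjusted p = 0.000222, 94.1-fold without sgn3 myb36 6 h replicate 2), a glutamate decarboxylase gene. They belonged at 10 h to UGT74E2 (AT1G05680, at least 1119.6-fold higher, adjusted p = 4.17e-07, 659-fold without sgn3 myb36 10 h replicate 2), a glucosyltransferase gene at 116 ± 87.1 CPM with 393 to 1921 counts in a library, and to ATHSP22.0 (AT4G10250, at least 397-fold higher, adjusted p = 2.2e-06). Among the largest falls at 3 h was TGG1 (AT5G26000, log2FC -3.91 ± 1.36, adjusted p = 0.0314, not called at adjusted p = 0.119, 0.12 and 0.0877 without sgn3 myb36 CK replicate 1 or sgn3 myb36 3 h replicates 2 and 3 in turn, -4.75 without sgn3 myb36 3 h replicate 1), a myrosinase of guard and myrosin cells. One at 6 h was RPK1 (AT1G69270, log2FC -3.94 ± 0.56, adjusted p = 1.84e-05), a receptor kinase gene. Sucrose export was represented at 10 h by SWEET11 (AT3G48740, log2FC -4.84 ± 1.37, adjusted p = 0.0067, not called at adjusted p = 0.0525 without sgn3 myb36 CK replicate 1, -5.49 without sgn3 myb36 10 h replicate 2). The light-harvesting gene with a large fall at 10 h was LHB1B1 (AT2G34430, log2FC -4.13 ± 1.34, adjusted p = 0.0153, not called at adjusted p = 0.0941, 0.0578 and 0.0568 without sgn3 myb36 CK replicate 1 or sgn3 myb36 10 h replicates 2 and 3 in turn, -5.24 without sgn3 myb36 10 h replicate 1). With the photosynthetic covariate, chosen after seeing the data, the log2FC of LHB1B1 was 0.17 (adjusted p = 0.854). A covariate of photosynthetic genes can absorb the change of such a gene.

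In sgn3 myb36, 6701 genes were called at 3 h (3899 higher, 2802 lower, 3075 by at least 2-fold), 9474 at 6 h (5062 higher, 4412 lower, 4767 by at least 2-fold) and 9431 at 10 h (4838 higher, 4593 lower, 4948 by at least 2-fold). The counts were 6221, 8827 and 8484 without the 3 chosen libraries, and 3646, 6125 and 5046 with the photosynthetic covariate. The 3 h count was 4203 without sgn3 myb36 3 h replicate 2.

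The responses of both genotypes were then compared gene by gene, each against its own control libraries. Across all 20405 tested genes, which are not independent replicates, their log2FC correlated at Pearson r = 0.329, 0.685 and 0.685 at 3, 6 and 10 h (Spearman 0.271, 0.707 and 0.691). The slope of the standardised major axis, sgn3 myb36 on Col-0, was 1.57, 1.52 and 1.52. Genes called in both numbered 650, 2946 and 3504, and 89.8%, 99.7% and 99.4% of them had the same sign. Of the 7332, 10128 and 10559 genes called in either, 65.6%, 90.8% and 89.7% had the same sign. Rising in both were 413, 1923 and 2156 genes, where independent lists would share 124.6, 565.6 and 676.2, and falling in both were 171, 1013 and 1326, where independent lists would share 86.4, 285.4 and 400.7. The 3 h response of sgn3 myb36 correlated at r = 0.622 and 0.627 with the Col-0 responses at 6 and 10 h.

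Genotypes were next compared at one time, to see what differed before and after inoculation. At CK, iron uptake genes were lower in sgn3 myb36. 17 of the 19 iron deficiency genes (17 adjusted over the list alone) were lower (camera adjusted p = 1.1e-16, adjusted p = 0.0687 with an estimated correlation), and FRO2 (AT1G01580, log2FC -6.43 ± 0.53, adjusted p = 2.52e-07), the ferric reductase of the root surface, stood at 248 ± 48.0 CPM in Col-0 and 2.83 ± 1.2 CPM in sgn3 myb36. 7 of the 8 Casparian strip genes (7 adjusted over the list alone) were lower and 1 was higher, with CASP1 (log2FC -4.28 ± 0.38) and PER64 (AT5G42180, log2FC -4.16 ± 0.53, adjusted p = 5.21e-05), the peroxidase of the strip, among the lower ones. The Casparian strip list gave adjusted p = 7.21e-07 by camera and 0.0894 with an estimated correlation. 11 of the 18 mitotic cell cycle genes (16 adjusted over the list alone) were higher, among them CYCB1;4 (AT2G26760, log2FC 0.92 ± 0.19, adjusted p = 0.00283), a mitotic cyclin. 3 were called without Col-0 CK replicate 2, 6 without Col-0 CK replicate 3 or sgn3 myb36 CK replicate 3 and 7 without sgn3 myb36 CK replicate 2. The mitotic cell cycle list gave adjusted p = 8.76e-09 by camera and 0.373 with an estimated correlation. 6 of the 9 cytokinin response genes (7 adjusted over the list alone, 3 without sgn3 myb36 CK replicate 2) were lower, such as the response regulator ARR6 (AT5G62920, log2FC -1.15 ± 0.23, adjusted p = 0.00305). The cytokinin response list gave adjusted p = 0.000833 by camera and 0.367 with an estimated correlation. 4 of the 7 morning clock genes (4 adjusted over the list alone, 1 without Col-0 CK replicate 2 or sgn3 myb36 CK replicate 3) were lower, including CCA1 (AT2G46830, log2FC -1.28 ± 0.24, adjusted p = 0.00161). The morning clock list gave adjusted p = 0.000575 by camera and 0.373 with an estimated correlation. 4 of the 16 abscisic acid genes (5 adjusted over the list alone) were lower, such as RD29A (AT5G52310, log2FC -2.0 ± 0.29, adjusted p = 0.000196). The abscisic acid list gave adjusted p = 0.0394 by camera and 0.416 with an estimated correlation, adjusted p = 0.113 and 0.0748 without Col-0 CK replicate 2 or sgn3 myb36 CK replicate 1 in turn.

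Furthest above Col-0 at CK by the naming rule was UMAMIT35 (AT1G60050, 172-fold higher, counting interval 30.4 to 6820.1, adjusted p = 0.00099), an amino acid transporter family gene. The immune regulator next to it was ACD6 (AT4G14400, 87.8-fold higher, counting interval 24 to 731, adjusted p = 0.0474, not called at adjusted p = 0.117, 0.154, 0.124, 0.188, 0.0568 and 0.0626 without Col-0 CK replicates 1, 2 and 3 or sgn3 myb36 CK replicates 1, 2 and 3 in turn, 22.2-fold without sgn3 myb36 CK replicate 1). Furthest below Col-0 was the iron-deficiency transcription factor BHLH100 (AT2G41240, at least 204-fold lower, adjusted p = 4.33e-06). The coumarin enzyme CYP82C4 (AT4G31940, log2FC -7.81 ± 0.57, adjusted p = 6.23e-08, -9.23 without sgn3 myb36 CK replicate 1) was also among the lowest. In all, 3076 genes were called at CK, 1302 higher and 1774 lower, 1059 by at least 2-fold. The share that was higher was 42.3%, and 31.6% with library totals as the only scaling. The count was 3705 without the 3 chosen libraries. It was 989 and 1759 without Col-0 CK replicates 2 and 3 in turn, and 1864 and 1461 without those of sgn3 myb36.

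At 3 h, immune and jasmonate genes stood higher in sgn3 myb36. 16 of the 29 pattern-triggered immunity genes (22 adjusted over the list alone) were higher, including WRKY33 (AT2G38470, log2FC 2.42 ± 0.46, adjusted p = 0.0019). 5 were called without Col-0 3 h replicate 1, 7 without sgn3 myb36 3 h replicate 2 and 8 without Col-0 3 h replicate 2. The pattern-triggered immunity list gave adjusted p = 1.41e-09 by camera and 0.394 with an estimated correlation. 14 of the 22 jasmonate genes (15 adjusted over the list alone) were higher, such as OPR3 (AT2G06050, log2FC 1.15 ± 0.15, adjusted p = 6.99e-05), a synthesis enzyme. 7 were called without Col-0 3 h replicate 1, 8 without Col-0 3 h replicate 2 and 9 without sgn3 myb36 3 h replicate 2. The jasmonate list gave adjusted p = 9.6e-09 by camera and 0.255 with an estimated correlation. Furthest above Col-0 were BARS1 (AT4G15370, at least 155-fold higher, adjusted p = 0.00198), a triterpene synthase gene, and CYP71B22 (at least 102-fold higher, adjusted p = 0.00616, 66.6-fold without sgn3 myb36 3 h replicate 1). Furthest below it were BHLH100 (851-fold lower, counting interval 152 to 33642, adjusted p = 2.81e-06) and BHLH38 (AT3G56970, 189-fold lower, counting interval 64.2 to 917, adjusted p = 1.09e-05). At 3 h, 2671 genes were called, 1768 higher and 903 lower, 1399 by at least 2-fold. The count was 3071 without the 3 chosen libraries, 1388 without Col-0 3 h replicate 1, 1317 without sgn3 myb36 3 h replicate 2 and 1660 without sgn3 myb36 3 h replicate 3.

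At 6 h, 12 of the 13 hypoxia genes (13 adjusted over the list alone) were higher in sgn3 myb36, such as the sucrose synthase SUS1 (AT5G20830, log2FC 3.69 ± 0.62, adjusted p = 0.00116). The hypoxia list gave adjusted p = 3.44e-14 by camera and 0.274 with an estimated correlation. 9 of the 16 aquaporin genes (13 adjusted over the list alone, 4 without sgn3 myb36 6 h replicate 2) were lower, including PIP1;1 (log2FC -1.33 ± 0.22). PIP1;5 and PIP2;4 were already lower at CK (log2FC -1.83 and -1.96) and PIP2;7 higher (0.78). No aquaporin gene was called in the 6 h interaction. The aquaporin list gave adjusted p = 1.61e-11 by camera and 0.255 with an estimated correlation. 6 of the 8 Casparian strip genes (7 adjusted over the list alone) were lower and 1 was higher, with CASP1 at log2FC -5.21 ± 0.35. The Casparian strip list, which holds SGN3 and MYB36, gave adjusted p = 7.2e-14 by camera. With an estimated correlation (0.0245) it was the 1 list call of 221 that held, and it partly tests the genotype labels. Furthest above Col-0 was SRO4 (log2FC 6.47 ± 1.2, adjusted p = 0.00348, 7.32 without Col-0 6 h replicate 1 and 5.80 without sgn3 myb36 6 h replicate 2). The hypoxia transcription factor gene HRE2 (AT2G47520, log2FC 4.96 ± 0.76, adjusted p = 0.000456, 5.74 without Col-0 6 h replicate 2 and 4.32 without sgn3 myb36 6 h replicate 2) was among the highest. Furthest below Col-0 were CYP82C4 (4154-fold lower, counting interval 745 to 164120, adjusted p = 2.62e-09) and IRT1 (AT4G19690, log2FC -8.34 ± 0.62, adjusted p = 2.49e-08), the main iron transporter of the root. IRT1 stood at 2.32 ± 1.14 CPM against 762 ± 108 in Col-0. At 6 h, 1114 genes were called, 661 higher and 453 lower, 725 by at least 2-fold. The count was 1745 without the 3 chosen libraries and 455 and 704 without Col-0 6 h replicates 1 and 3 in turn. It was 395 and 481 without sgn3 myb36 6 h replicates 2 and 3.

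At 10 h, 6 of the 7 heat shock genes (7 adjusted over the list alone) were higher in sgn3 myb36, such as HSP101 (log2FC 3.47 ± 0.36, adjusted p = 1.16e-06), at 296 ± 33.7 CPM against 26.6 ± 10.3. The heat shock list gave adjusted p = 5.27e-11 by camera and 0.0899 with an estimated correlation. All 13 xenobiotic detoxification genes were higher, including GSTU24 (log2FC 3.20 ± 0.36, adjusted p = 3.65e-06) (13 adjusted over the list alone). The xenobiotic detoxification list gave adjusted p = 1.1e-16 by camera and 0.0873 with an estimated correlation. 13 of the 16 aquaporin genes (14 adjusted over the list alone) were lower, among them PIP1;1 (log2FC -2.59 ± 0.23, adjusted p = 1.51e-07). The aquaporin list gave adjusted p = 2.54e-17 by camera and 0.0961 with an estimated correlation. 6 of the 9 genes of mitochondrial dysfunction and cyanide detoxification (7 adjusted over the list alone) were higher, among them AOX1A (log2FC 3.63 ± 0.41, adjusted p = 3.38e-06). The mitochondrial dysfunction list gave adjusted p = 4.57e-07 by camera and 0.204 with an estimated correlation. Furthest above Col-0 were sks8 (AT1G21850, at least 82.9-fold higher, adjusted p = 0.000851) and HSP23.6-MITO (AT4G25200, log2FC 7.83 ± 0.80, adjusted p = 1.18e-06, 10.64 without Col-0 10 h replicate 3). Furthest below it was CYP82C4 (log2FC -9.21 ± 0.56, adjusted p = 1.66e-09, -8.63 without sgn3 myb36 10 h replicate 2 and -14.20 without sgn3 myb36 10 h replicate 3). The peroxidase gene PER64 (log2FC -7.59 ± 0.66, adjusted p = 1.51e-07, -8.29 without sgn3 myb36 10 h replicate 1) was among the lowest. At 10 h, 3013 genes were called, 1492 higher and 1521 lower, 1616 by at least 2-fold. The count was 2349 without the 3 chosen libraries, 1940 with the photosynthetic covariate, 1845 without Col-0 10 h replicate 1 and 1666 without Col-0 10 h replicate 2.

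**Figure D4:**
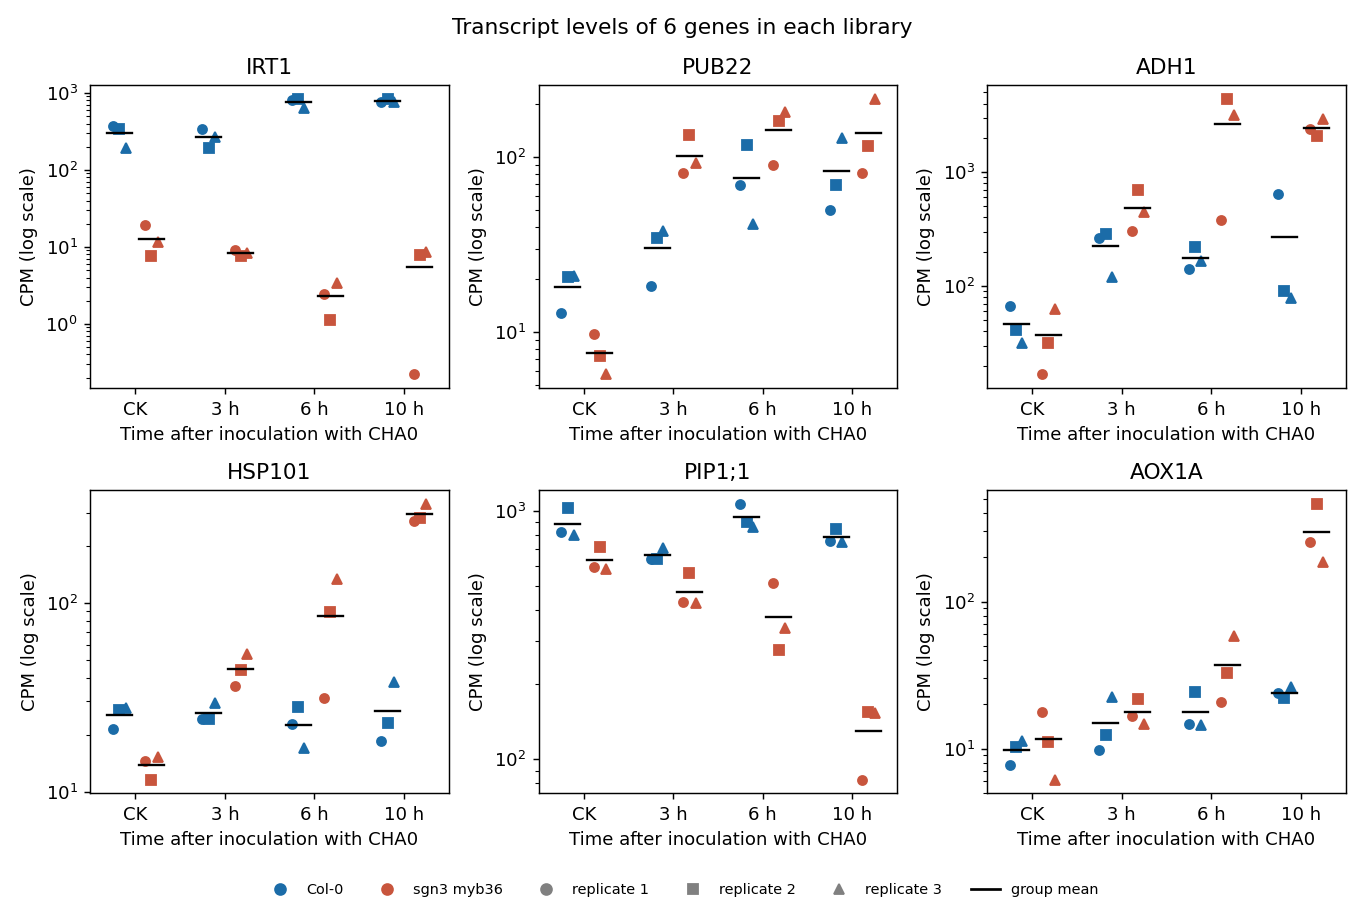
CPM on a log scale of IRT1, PUB22, ADH1, HSP101, PIP1;1 and AOX1A against time after inoculation, 1 point per library and a black bar for the mean of each group of 3. IRT1 means are 762 CPM in Col-0 and 2.32 CPM in sgn3 myb36 at 6 h, and HSP101 means are 26.6 and 296 CPM at 10 h.

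Whether the response itself differed between genotypes was tested by the interaction, the change from CK in sgn3 myb36 minus the change in Col-0. A positive value, written as rose more, is a larger rise or a smaller fall in sgn3 myb36, and the genotype difference at CK uses the same control libraries. At 3 h, 6 of the 29 pattern-triggered immunity genes (7 adjusted over the list alone) rose more in sgn3 myb36, including PUB22 (log2 difference 3.00 ± 0.61, adjusted p = 0.0054). At most 3 were called without Col-0 3 h replicate 1 or 2 or Col-0 CK replicate 2 or 3 or sgn3 myb36 3 h replicate 2 or sgn3 myb36 CK replicate 2 or 3. The pattern-triggered immunity list gave adjusted p = 1.23e-06 by camera and 0.442 with an estimated correlation. 6 of the 20 salicylic acid genes (11 adjusted over the list alone, 10 without sgn3 myb36 CK replicate 1) rose more, such as PAD4 (log2 difference 1.81 ± 0.39, adjusted p = 0.00741). The salicylic acid list gave adjusted p = 5.11e-05 by camera and 0.442 with an estimated correlation. 5 of the 22 jasmonate genes (5 adjusted over the list alone) rose more, among them OPR3 (log2 difference 1.1 ± 0.21, adjusted p = 0.00431). At most 3 were called without Col-0 3 h replicate 1 or 2 or Col-0 CK replicate 2 or 3 or sgn3 myb36 3 h replicate 1 or 2 or sgn3 myb36 CK replicate 2 or 3. The jasmonate list gave adjusted p = 0.00101 by camera and 0.426 with an estimated correlation. 4 of the 18 mitotic cell cycle genes (6 adjusted over the list alone) fell more, such as CDKB2;1 (log2 difference -1.11 ± 0.22, adjusted p = 0.00465). 2 were called without Col-0 3 h replicate 1 or sgn3 myb36 CK replicate 3. The mitotic cell cycle list gave adjusted p = 4.18e-05 by camera and 0.443 with an estimated correlation. The largest positive differences by rule included BARS1 (0.0375 to 14.9 CPM in sgn3 myb36 and 0.532 to 0 CPM in Col-0, adjusted p = 0.0175, not called at adjusted p = 0.122 without Col-0 CK replicate 2). Among the largest negative ones was AGP26 (AT2G47930, log2 difference -3.53 ± 0.84, 4.57 to 1.07 CPM in sgn3 myb36 and 2.64 to 7.21 CPM in Col-0, adjusted p = 0.0118). In all, 2453 genes were called at 3 h, 1552 positive and 901 negative. The count was 3194 without the 3 chosen libraries, 1013 without Col-0 CK replicate 2, 1433 without Col-0 CK replicate 3, 1584 without Col-0 3 h replicate 1, 1595 without Col-0 3 h replicate 2, 1440 without sgn3 myb36 CK replicate 3 and 1165 without sgn3 myb36 3 h replicate 2.

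At 6 h, 10 of the 13 hypoxia genes (13 adjusted over the list alone) rose more in sgn3 myb36, but at most 3 without replicate 2 or 3 of any of the 4 groups. They included PDC1 (log2 difference 4.46 ± 0.88, adjusted p = 0.0277, not called in 7 of the 12 fits without 1 of its libraries, adjusted p up to 0.0859 without Col-0 6 h replicate 3). The hypoxia list gave adjusted p = 3.71e-11 by camera and 0.367 with an estimated correlation. This list stood apart in sgn3 myb36 6 h replicate 1. The largest positive differences by rule included NIP2;1 (AT2G34390, log2 difference 6.93 ± 1.18, 0.229 to 47.4 CPM in sgn3 myb36 and 1.68 to 2.61 CPM in Col-0, adjusted p = 0.0215, not called at adjusted p = 0.062, 0.0859, 0.0501 and 0.0546 without Col-0 CK replicate 2, Col-0 6 h replicate 3, or sgn3 myb36 6 h replicates 2 and 3 in turn), a channel of the aquaporin family. The alcohol dehydrogenase gene of fermentation was another, ADH1 (AT1G77120, log2 difference 4.27 ± 1.03, 36.8 to 2665 CPM in sgn3 myb36 and 46.6 to 176 CPM in Col-0, adjusted p = 0.0486, not called in 11 of the 12 fits without 1 of its libraries, adjusted p up to 0.134 without sgn3 myb36 6 h replicate 2). The largest negative one was that of IRT1 (log2 difference -3.79 ± 0.71, 12.8 to 2.32 CPM in sgn3 myb36 and 302 to 762 CPM in Col-0, adjusted p = 0.0215, not called at adjusted p = 0.0671, 0.0514, 0.0859, 0.0739 and 0.0546 without Col-0 CK replicates 2 and 3, Col-0 6 h replicate 3, or sgn3 myb36 6 h replicates 2 and 3 in turn). In all, 186 genes were called, 173 positive and 13 negative. The count was 1884 without the 3 chosen libraries and 23 with the photosynthetic covariate. It moved with each of the 12 libraries of the contrast. Without replicates 1, 2 and 3 in turn, Col-0 CK gave 405, 6 and 35, and Col-0 6 h 426, 90 and 0. Likewise sgn3 myb36 CK gave 509, 50 and 51, and sgn3 myb36 6 h 1352, 1 and 1. With every library, 3638 genes had an unadjusted p under 0.05, and DESeq2 called 791 beside edgeR's 186.

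At 10 h, 11 of the 13 xenobiotic detoxification genes (13 adjusted over the list alone, 7 without Col-0 CK replicate 2) rose more in sgn3 myb36, including GSTU24 (log2 difference 3.31 ± 0.51, adjusted p = 0.000824). The xenobiotic detoxification list gave adjusted p = 2.76e-17 by camera and 0.0873 with an estimated correlation. 5 of the 7 heat shock genes (6 adjusted over the list alone) rose more, including HSP101 (log2 difference 4.34 ± 0.49, adjusted p = 5.88e-05). The heat shock list gave adjusted p = 2.92e-12 by camera and 0.0873 with an estimated correlation. 9 of the 16 aquaporin genes (12 adjusted over the list alone) fell more, among them PIP1;1 (log2 difference -2.11 ± 0.30, adjusted p = 0.000464) and TIP2;2 (log2 difference -3.04 ± 0.39, adjusted p = 0.000117). The aquaporin list gave adjusted p = 2.09e-12 by camera and 0.241 with an estimated correlation. 7 of the 17 suberin genes (13 adjusted over the list alone) rose more, such as FAR5 (log2 difference 2.47 ± 0.45, adjusted p = 0.00349). 3 were called without Col-0 10 h replicate 2 or sgn3 myb36 10 h replicate 2, 4 without Col-0 10 h replicate 1, 11 without Col-0 10 h replicate 3 and 12 without sgn3 myb36 10 h replicate 1. The suberin list gave adjusted p = 4.18e-10 by camera and 0.255 with an estimated correlation. 3 of the 9 genes of mitochondrial dysfunction and cyanide detoxification (4 adjusted over the list alone) rose more, such as AOX1A (log2 difference 3.38 ± 0.56, adjusted p = 0.00176). The mitochondrial dysfunction list gave adjusted p = 6.12e-06 by camera and 0.259 with an estimated correlation. The largest positive differences by rule included ATHSP22.0 (0 to 40.9 CPM in sgn3 myb36 and 0.176 to 0.163 CPM in Col-0, adjusted p = 0.0162, not called at adjusted p = 0.301 without Col-0 CK replicate 2). Among the largest negative ones was EXPA5 (AT3G29030, log2 difference -3.74 ± 0.96, 4.99 to 0.794 CPM in sgn3 myb36 and 2.35 to 5.09 CPM in Col-0, adjusted p = 0.0315, not called in 7 of the 12 fits without 1 of its libraries, adjusted p up to 0.0955 without Col-0 CK replicate 2), an expansin gene. In all, 742 genes were called at 10 h, 609 positive and 133 negative. The count was 1004 without the 3 chosen libraries and 241 with the photosynthetic covariate. Without replicates 2 and 3 in turn it was 358 and 478 for Col-0 CK and 457 and 444 for sgn3 myb36 10 h. Without Col-0 10 h replicates 1 and 2 in turn it was 460 and 358. A joint test of the 3 interactions called 1683 genes, 2507 without the 3 chosen libraries, 806 without Col-0 CK replicate 2, 1004 without Col-0 CK replicate 3, 1112 without Col-0 3 h replicate 1, 1012 without sgn3 myb36 CK replicate 3, 989 without sgn3 myb36 3 h replicate 2 and 2589 without sgn3 myb36 6 h replicate 1.

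**Figure D5:**
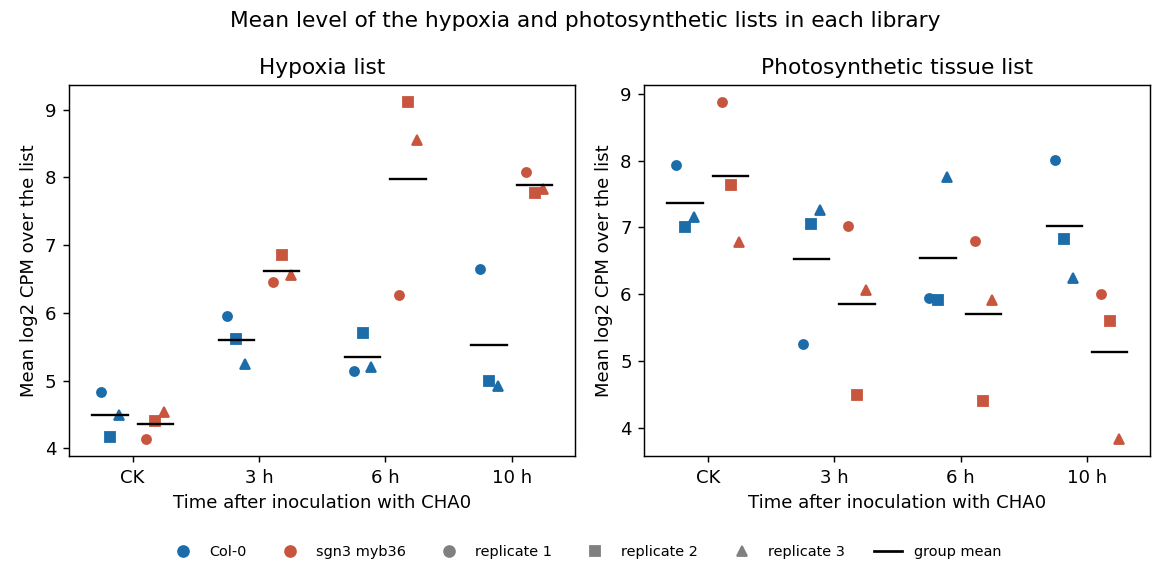
Mean log2 CPM of the hypoxia list and of the photosynthetic tissue list against time after inoculation, 1 point per library and a black bar for the mean of each group of 3. In sgn3 myb36 6 h the hypoxia list lies at 6.27, 9.11 and 8.55 in replicates 1, 2 and 3, and in sgn3 myb36 CK the photosynthetic list lies at 8.88, 7.63 and 6.78.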

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

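The tests of the photosynthetic fall, of the hypoxia genes in sgn3 myb36 6 h replicate 1 and of earlier timing were chosen only after the result was seen, as were the splits of the libraries for the 10 pair comparisons and the interaction at 3 h.

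The genotypes differed in their response by the interaction test, which called 2453 genes at 3 h, 186 at 6 h, 742 at 10 h and 1683 in the joint test. Without Col-0 CK replicate 2 the counts at 3 h, at 10 h and in the joint test were 1013, 358 and 806. Without Col-0 6 h replicate 3 edgeR called 0 at 6 h. With every library, 3638 genes had an unadjusted p under 0.05 there and DESeq2 called 791. Other assignments of the same libraries were tested 100 at a time, the real one included. At 3 h 1 of 100 splits gave as many genes and the highest other gave 1383, and in the joint test 2 did and the highest other gave 1817. At 6 h 7 of 100 did and the highest other gave 3248, and at 10 h 5 did and the highest other gave 4738. A share under 0.05 had been set as the value against chance, which only the 3 h and joint tests met. Chance is not thereby excluded there, because re-drawn groups mix the genotypes, which can widen their spread. The median of the other splits was 0 in each test. The splits at 6 and 10 h with several times the real count point to a structure of the samples, part of which is the genotype difference itself, since the splits re-drew genotypes within each time and can carry it into the interaction.

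For the 10 pair comparisons, 3 libraries against 3 make 10 splits, too few for a share under 0.05. In each 1 of 10 reached the real count. The others mix both groups, which can widen their spread, so low counts do not exclude chance. Real counts and the highest of the others were 1281 and 1, 3600 and 0, and 4632 and 0 in Col-0 at 3, 6 and 10 h. They were 6701 and 1, 9474 and 392, and 9431 and 1 in sgn3 myb36, and 3076 and 1, 2671 and 0, 1114 and 122, and 3013 and 0 between the genotypes at CK, 3, 6 and 10 h.

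By camera adjusted p, 21 lists differed in response, each given at its smallest p over the 3 times, higher or lower in sgn3 myb36. They were at 3 h jasmonate (0.00101), monolignols and lignin (0.000158), glutamine and amino acid metabolism and transport (0.0091) and root hair (0.0267) higher, at 6 h salicylic acid (4.57e-07), ethylene (0.000155), hypoxia (3.71e-11), touch, handling and cold (0.0134), camalexin and tryptophan-derived defence (0.00111) and indole glucosinolates (0.0034) higher, with mitotic cell cycle (7.23e-08) and Casparian strip (0.00316) lower, and at 10 h pattern-triggered immunity (3.89e-07), xenobiotic detoxification (2.76e-17), heat shock (2.92e-12), suberin (4.18e-10), mitochondrial dysfunction and cyanide detoxification (6.12e-06), auxin response (0.0261) and circadian clock, afternoon and evening (0.00737) higher, with aquaporins (2.09e-12) and photosynthetic tissue (4.12e-05) lower. With an estimated correlation their adjusted p was 0.0873 to 0.536. The call of touch, handling and cold ended at adjusted p = 0.149 and 0.066 without Col-0 6 h replicate 3 or sgn3 myb36 CK replicate 2 in turn. The call of root hair ended at adjusted p = 0.0538, 0.0527 and 0.0841 without Col-0 3 h replicate 2, sgn3 myb36 CK replicate 3, or sgn3 myb36 3 h replicate 2 in turn. The call of auxin response ended at adjusted p = 0.0932, 0.0614, 0.165 and 0.0803 without Col-0 CK replicate 2, Col-0 10 h replicate 2, sgn3 myb36 CK replicate 3, or sgn3 myb36 10 h replicate 2 in turn.

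Named genes whose response differed between genotypes are given with edgeR adjusted p of the interaction, and with the highest adjusted p without 1 library where that ended the call. At 3 h they were BARS1 (0.0175, up to 0.122 without Col-0 CK replicate 2), ACS11 (0.00431), PRXCA (0.0275, up to 0.13 without Col-0 CK replicate 1), SHB1 (0.00226), AGP26 (0.0118), STY1 (0.00204), SHI (0.00269), GA2OX4 (0.0174, up to 0.056 without sgn3 myb36 3 h replicate 2), PUB22 (0.0054), PAD4 (0.00741), OPR3 (0.00431) and CDKB2;1 (0.00465). At 6 h they were NIP2;1 (0.0215, up to 0.0859 without Col-0 6 h replicate 3), LSU3 (0.0118, up to 0.0521 without Col-0 6 h replicate 3), ACS11 (0.0318, up to 0.0972 without Col-0 6 h replicate 3), ADH1 (0.0486, up to 0.134 without sgn3 myb36 6 h replicate 2), IRT1 (0.0215, up to 0.0859 without Col-0 6 h replicate 3), UCC1 (0.0418, up to 0.135 without sgn3 myb36 6 h replicate 3), YUC9 (0.0431, up to 0.155 without Col-0 CK replicate 2), PRS2 (0.0323, up to 0.107 without sgn3 myb36 6 h replicate 2) and PDC1 (0.0277, up to 0.0859 without Col-0 6 h replicate 3). At 10 h they were ATHSP22.0 (0.0162, up to 0.301 without Col-0 CK replicate 2), HSP21 (0.00295), MYB108 (0.0157), LAC12 (0.00384), EXPA5 (0.0315, up to 0.0955 without Col-0 CK replicate 2), CYP710A3 (0.0255, up to 0.0635 without Col-0 10 h replicate 2), PER64 (0.0415, up to 0.129 without sgn3 myb36 10 h replicate 2), TIP2;3 (0.00433), GSTU24 (0.000824), HSP101 (5.88e-05), PIP1;1 (0.000464), TIP2;2 (0.000117), FAR5 (0.00349) and AOX1A (0.00176).

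Photosynthetic genes fell in sgn3 myb36, 13 of 15 at 10 h. Shoot tissue in some root libraries is a candidate explanation, since deviations from the group mean of these 15 genes and of 6 shoot epidermis and guard cell genes correlated over 24 libraries at Pearson r = 0.73 (2-sided permutation p = 0.00069, libraries permuted within groups), Spearman rho = 0.716 (permutation p = 0.00091), and r = 0.713 without the 2 farthest libraries and 0.691 without TGG1, with no other pair of lists tested. The most abundant markers, CER3 and TGG1, stood at 43.6 ± 8.31 and 28.1 ± 22.4 CPM at sgn3 myb36 CK and at 32.3 ± 6.13 and 39.6 ± 34.6 CPM at Col-0 CK, where all 6 markers passed the expression filter of the root data and at most 2 fell in sgn3 myb36 at any time. A high level in sgn3 myb36 CK replicate 1 may account for part of the count, because 5 genes fell without that library. A change in root cells cannot be told apart from these, as the marker genes had a median log2FC of -1.95 at 10 h (-2.08 with genes at their bound) that ranged from -3.79 to -0.22 without 1 library.

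Hypoxia genes lay at 6.27 log2 CPM in sgn3 myb36 6 h replicate 1 and at 9.11 and 8.55 in replicates 2 and 3, with 13 of 13 genes below both. A wrong genotype label is argued against by its 6 Casparian strip genes, at -0.518 log2 CPM where the lowest Col-0 library lay at 3.07. A swap with a 3 h library would need a partner near the other 6 h libraries, and sgn3 myb36 3 h libraries lay at 6.45 to 6.85. A state shared by all transcripts alike, such as depth, is argued against by the median difference of -2.24, its size at percentile 100 of 10000 matched lists (highest 0.789), where the unfolded protein response list moved by 0.106. Other lists moved far as well, heat shock by 1.80, photosynthetic tissue by 1.55 and phloem by 1.23, so the shift was not confined to hypoxia genes. The hypoxia list was picked for its low level in this library, so its percentile is no independent test. A state that moved some genes more than others, RNA quality included, stays open. The library lay at 17.0 on the first component, against 46.1 and 45.2, and the 3 h libraries at 17.0 to 31.0. No biological explanation of this likeness to 3 h was tested, as the design names none for 1 library.

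The response of sgn3 myb36 at 3 h resembled later Col-0 responses, with r across genes, which are not independent replicates, of 0.622 and 0.627 to Col-0 6 and 10 h against 0.329 to Col-0 3 h. Its 6 and 10 h responses also correlated less with Col-0 3 h (0.323 and 0.355) than with Col-0 6 and 10 h (0.630 to 0.707). Noise in the smaller Col-0 3 h response as the whole cause is argued against by the 1281 genes called there, over which r was 0.757 and 0.748 against 0.624, a gap of 0.124 (0.103 to 0.144 without 1 library). Earlier timing in sgn3 myb36 may explain the gap of 0.294 over all genes (0.204 at the lowest without 1 library). A response of another kind in sgn3 myb36, or a Col-0 3 h response unlike all 3 of its responses, stays open.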

How the results depend on the processing

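Leaving out 3 libraries chosen by their photosynthetic or hypoxia level and the photosynthetic covariate were tests chosen only after the result was seen. The counts of called genes moved by less than 1.5 times in all 14 comparisons with DESeq2 size factors, library totals only, at least 50 counts in 3 samples, or nuclear protein-coding genes only, and no scaling moved the median of all genes by over 0.1. Of 870 values of named genes, 860 kept direction and call with DESeq2 size factors, 852 with library totals, 849 without a filter, 808 without the 3 chosen libraries, 751 with the covariate and 843 with DESeq2, and of 854 values 846 did with the stricter filter. Of 221 called list tests, 1 held with an estimated correlation, 218 with library totals, 211 without the 3 chosen libraries and 192 with the covariate. Another method, fry, called 171 of the 221, but it tests whether the genes of a list move one way and not whether they differ from other genes, so this count is no support for the difference that camera tests. Leaving out 1 library kept 5175 of 6096 gene values and 1486 of 1602 list calls.

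With 1 library left out, the counts ran from 585 to 1132, 1533 to 3973 and 2804 to 3851 in Col-0 at 3, 6 and 10 h, 4203 to 6132, 7314 to 9488 and 7304 to 9440 in sgn3 myb36, 989 to 3580, 1317 to 2177, 395 to 1604 and 1666 to 2401 between genotypes at CK, 3, 6 and 10 h, and 1013 to 2892, 0 to 1352, 358 to 992 and 806 to 2589 for the interactions at 3, 6 and 10 h and at any time. At an adjusted p under 0.01 the counts were 561, 1573 and 2231 in Col-0, 3787 in sgn3 myb36 at 3 h, 1023, 941, 433 and 1417 between genotypes, and 499, 0, 220 and 337 for the interactions. With a log2FC of at least 1 they were 611, 1608 and 2098 in Col-0, 3075, 4767 and 4948 in sgn3 myb36, 1059, 1399, 725 and 1616 between genotypes and 1600 for the interaction at 3 h. Fewer genes pass a stricter threshold by construction.

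With the covariate, 3646, 6125 and 5046 genes were called in sgn3 myb36, 1940 between genotypes at 10 h, and 23 and 241 for the interactions at 6 and 10 h. Without the 3 chosen libraries, 1745 were called between genotypes at 6 h and 1884 for the interaction at 6 h. With only the groups compared, edgeR called 1935 and 402 between genotypes at CK and 6 h and 0 for the interaction at 6 h, where all groups gave 186 and 3638 genes had an unadjusted p under 0.05. DESeq2 called 791, 1284 and 3165 for the interactions at 6 h, 10 h and any time, and edgeR without a filter 332 at 6 h. The cause of these shifts was not tested.

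LHB1B1 in sgn3 myb36 at 10 h reversed with the covariate (log2FC 0.17, adjusted p = 0.854, where its other alternatives gave 0.0061 to 0.0941), which can absorb a photosynthetic change. SGN3 was called at 6 h by DESeq2 (log2FC -0.85, adjusted p = 0.0447, where its other alternatives gave 0.0529 to 0.244), and at CK its log2FC ran from -1.37 to -0.88 with 1 library left out. The correlation between genotypes was 0.459, 0.788 and 0.781 at 3, 6 and 10 h over genes with an average log2 CPM of at least 5, and over all genes it ran from 0.206 to 0.357, 0.591 to 0.682 and 0.582 to 0.671 with 1 library left out.

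With a replicate block, all 14 counts stayed within 1.5 times, 849 of 870 gene values and 220 of 221 list calls were kept. Over 84 pairs of same-numbered libraries of different groups, the correlation of deviations from the group means ran from -0.357 to 0.329 (median 0.034, and -0.013 for other pairs), so the numbers were not taken to pair the samples, since not every pair correlated above 0.1. Of 24 libraries 15 correlated best with one of their own number, where chance gives 8, a hint from the data that the design does not record. Depth limits low genes, since 3 counts in a library stand for 0.276 to 0.341 CPM.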

Other observations

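The sulfur deficiency, sugar starvation, ferritin and shoot lists and the test of the triterpene neighbourhood were chosen only after the result was seen, as were the genes named from them. Of 10 sulfur deficiency genes, 4, 5 and 5 rose in Col-0 at 3, 6 and 10 h (6, 6 and 5 adjusted over the list alone) and 8, 9 and 9 in sgn3 myb36 (9, 9 and 9 adjusted over the list alone). The sulfate reductase gene APR3 (AT4G21990) went from 37.8 ± 8.30 to 284 ± 35.4 CPM in sgn3 myb36 at 10 h (log2FC 2.91 ± 0.25, adjusted p = 6.12e-08), and the sulfate transporter gene SULTR1;2 (AT1G78000) from 195 ± 31.5 to 583 ± 153 CPM (log2FC 1.58 ± 0.25, adjusted p = 3.1e-05). At 10 h 1 fell in Col-0. At CK 2 of them (3 adjusted over the list alone, 1 without Col-0 or sgn3 myb36 CK replicate 2, 4 without sgn3 myb36 CK replicate 1) were already lower in sgn3 myb36. The interaction, which shares those CK libraries, was positive for 2, 3 and 5 of these genes at 3, 6 and 10 h, and with 1 library left out for 1 to 3, 0 to 7 and 3 to 6 by edgeR (7 at 6 h at an unadjusted p under 0.05 with every library), lowest at 6 h without Col-0 6 h replicate 3 and at 10 h without Col-0 CK replicate 2.

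Of 11 genes induced by sugar starvation, 9, 9 and 10 fell in Col-0 at 3, 6 and 10 h, and 7 and 9 in sgn3 myb36 at 6 and 10 h (11, 10, 10, 8 and 10 adjusted over the list alone, 4 at 6 h without sgn3 myb36 CK or 6 h replicate 1). DIN10 (AT5G20250) went from 2172 ± 508 to 679.6 ± 152 CPM in Col-0 at 3 h (log2FC -1.68 ± 0.31, adjusted p = 0.00189) and from 1212 ± 225 to 1250 ± 241 CPM in sgn3 myb36 (log2FC 0.04 ± 0.30, adjusted p = 0.927). In sgn3 myb36 at 3 h 0 of 11 were called by edgeR (2 fell at an unadjusted p below 0.05, 0 adjusted over the list alone, median log2FC -0.10). At CK 3 (8 adjusted over the list alone, 0 without CK replicate 2 or 3 of either genotype, 5 and 6 without replicate 1 of Col-0 and of sgn3 myb36, 8 at an unadjusted p under 0.05 with every library) were already lower in sgn3 myb36, with a median log2FC of -0.84. The interaction at 3 h, which shares those CK libraries, was positive for 5 of the 11 (8 without sgn3 myb36 CK replicate 1). Less starvation, or more sugar, in inoculated roots may explain the falls, and time alone is not excluded. 6 genes of the list whose values had not been looked at had a median log2FC of -2.22 in Col-0 at 10 h. Sugar was not measured here.

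A run of 8 neighbouring tested genes from CYP702A2 to CYP705A4, which holds cytochrome P450 genes and 2 triterpene synthase genes, was called higher in 5 genes in Col-0 and 6 in sgn3 myb36 at 10 h. Its median log2FC at 10 h was above 99.95% of 20315 such runs in sgn3 myb36 and 99.99% in Col-0, so a shared rise of the neighbourhood is a candidate explanation, although it was tested on the genes that drew attention to it. Within it, BARS1 stood on average at 0.532 CPM at CK and 32.7 CPM at 10 h in Col-0, and at 0.0375 and 25.3 CPM in sgn3 myb36. The neighbouring triterpene synthase gene PEN1 (AT4G15340) stood at 124 and 98.9 CPM in Col-0 and 47.8 and 29.5 CPM in sgn3 myb36.

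The lower iron uptake genes of sgn3 myb36 at CK could come from a higher iron status of its roots, which would raise ferritin genes. By edgeR 0 of 3 ferritin genes were called higher at CK and 0 rose at an unadjusted p under 0.05, with log2FC 0.11 ± 0.15, 0.21 ± 0.25 and 0.13 ± 0.29 and adjusted p = 0.679, 0.604 and 0.817 for FER1, FER3 and FER4. The explanation stays open. That no ferritin gene be called was set beforehand as the value against it, which was too weak a bound, since all 3 values are positive and their standard errors leave room for a rise. Iron was not measured here.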
